A study of Mus musculus with 4 samples.

How the data were processed

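Messenger RNA was sequenced from 4 subcutaneous 9464D-GD2 neuroblastoma tumours grown in female C57BL/6 mice. Per the labels' protocols, 2 tumours came from mice dosed with 25 µg dinutuximab and 2 from mice dosed with 25 µg dinutuximab plus 20 µg small extracellular vesicles (sEVs) made by 9464D-GD2 cells. Dosing was 2 times per week for 5 treatments. Tissue was flash frozen, RNA was extracted with an RNeasy Mini kit, libraries were made with an Illumina stranded mRNA kit, and each library was run on 2 lanes, per the labels' protocols. The labels number the tumours 3 and 4 in each group without saying what the number means.

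The authors deposited raw counts per Ensembl gene for 43432 genes, as a table of the whole series and as a table per sample. All 173728 values were equal in both sources. The submitters' processing notes name STAR, SAMtools, HTSeq and the mm10 build. Their versions, the annotation release, the counting mode and the strand setting were not given in the sources used here. Counts of genes that overlap on opposite strands, and of near-identical gene copies, are therefore uncertain. Gene names and coordinates came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, which named 42548 IDs and left 884 without a name. The unnamed IDs took between 0.0945% and 0.100% of the counts of a library and stayed in the tests. Every line of the deposited tables names a gene.

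The deposited counts were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr at its default settings, which kept 13823 genes. Libraries were scaled with TMM factors, which ranged from 0.976 to 1.02. Each gene was tested for a difference between the groups with the quasi-likelihood F test, in a model with the group as its only term, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. Levels are given as CPM, the count scaled to the TMM-adjusted library size, with the SD over the 2 tumours of a group. Log2 fold changes are sEV group over dinutuximab group, with the standard error (SE) from the model. The common biological coefficient of variation was 0.150. With 2 tumours against 2, the smallest exact two-sided permutation p of a single gene is 0.333, so no such test was used.

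For sets of genes, 36 lists holding 525 different genes were tested, 404 of which passed the filter. Itgam, Cma1, Fcgr1 and Vegfa each stood in more than 1 list. The lists cover immune and stromal cell types, interferon and antigen presentation programmes, neuroblastoma cell states, ganglioside synthesis, growth, stress, vesicle release and RNA quality. Each list was compared with the other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, and adjusted with the Benjamini-Hochberg method over the 36 lists. The test was repeated with the correlation estimated from the data, and with fry, which asks whether the genes of a list move, on balance, in 1 direction. With 4 libraries the estimated correlation is itself imprecise.

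The comparison, the lists, the genes to be named and all alternatives but 1 were fixed before the data were examined. Genes to be named were the 6 of lowest adjusted p and the 6 of largest change among called genes per direction, up to 3 called members of each list, and 16 genes of interest whatever their result. Where fewer than 6 genes passed in a direction, the 6 of lowest unadjusted p in it were named as values that did not pass, leaving out predicted genes and receptor gene segments. Other list members were named as examples after their values were seen. Some list members are not reported here.

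The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, 3 other scalings, 2 other filters on low counts, robust dispersions, an adjusted p threshold of 0.1, a minimum fold of 1.5, the tumour number as a block, the 2 other list tests, library sizes without mitochondrial genes and the 20 most abundant genes, the tables per sample, and leaving out each library in turn. Leaving out the genes that collect ribosomal RNA reads was added after their levels were seen. Where 1 library is left out, the lone library of its group is assumed to vary like the other group.

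The tests were tested on simulated data, in 5 simulations of this comparison with 200 changed genes each and between 13590 and 13610 genes in the step. The changed genes were drawn only from genes with a mean above 5 CPM, so recovery at lower levels was not tested. Among them the edgeR test recovered 43% of genes changed 2-fold and 95.8% of genes changed 4-fold, and 5.71% of its calls were false. DESeq2 recovered 77.4% and 98.6%, and 21.6% of its calls were false. With no gene changed, edgeR made 0 calls in each simulation and DESeq2 a mean of 15.6, between 10 and 26. Camera with the preset correlation called a list shifted 1.4-fold in 5 of 5 simulations and called 3 of 175 unshifted lists. With an estimated correlation it called the shifted list in 0 of 5. Genes were simulated independently of each other, which favours the preset correlation.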

Results

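RNA was sequenced from 4 subcutaneous tumours of female mice, 2 from mice given dinutuximab and 2 from mice given dinutuximab plus small extracellular vesicles (sEVs). The tumours grew from 9464D-GD2 cells, a mouse neuroblastoma line that carries the ganglioside GD2 on its surface. Its parent 9464D comes from a mouse with a human MYCN transgene. Dinutuximab is a monoclonal antibody against GD2 used in neuroblastoma therapy, and sEVs are membrane vesicles released by cells, here by the tumour line itself. The series title links sEVs with resistance to antibody therapy against GD2, and the comparison asks how added sEVs altered gene expression in tumours under the antibody. The dinutuximab libraries held 26312447 and 24452699 counts and the sEV libraries 26164711 and 28187573, with between 18818 and 19164 genes detected. The series design calls the 2 tumours of a group biological replicates. The chi-square per degree of freedom over genes was 23.9 and 26.6 between libraries of the same group, and from 22.7 to 35.6 between libraries of different groups. On the main axis of a principal component analysis (42.4% of the variance), sEV replicate 3 lay at 35.2 and the other 3 libraries between -16.3 and -5.96.

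The 2 tumours given sEVs had lower expression of hypoxia and glycolysis genes as a group than the 2 given dinutuximab alone. Their red blood cell and alternatively activated macrophage genes were higher as groups, while no single gene passed the test. Over the 17 tested hypoxia and glycolysis genes the median log2 fold change was -0.43 (SD over genes 0.42, n = 2 tumours per group), or 1.35-fold lower. Slc2a1, which encodes the glucose transporter GLUT1, averaged 526 ± 80.7 CPM with dinutuximab and 267 ± 6.00 CPM with added sEVs (SD, n = 2). Red blood cell genes had a median of 1.19 (SD over genes 0.64, n = 2 tumours per group), or 2.28-fold higher. Alternatively activated macrophage genes had a median of 0.34 (SD over genes 0.40, n = 2 tumours per group), and among them Clec10a, a macrophage lectin, averaged 14.7 ± 2.80 CPM with dinutuximab and 30.0 ± 0.770 CPM with added sEVs (SD, n = 2). These 3 lists were called by camera with a preset correlation of 0.01 (adjusted p of 1.3e-13, 1.9e-10 and 4.4e-06). The estimated correlations were 0.201, 0.325 and 0.122, and with them the calls were lost (camera adjusted p = 0.399, 0.399 and 0.510). Camera with the preset correlation also called these 3 lists lower in tumours numbered 4 than 3 (adjusted p = 0.0485, 0.0302 and 0.0014). In the same tumours immediate early and heat shock genes, which respond to tissue handling, were lower as a list (median -0.37, camera adjusted p = 2.2e-08; adjusted p = 0.399 with an estimated correlation). The 9 genes that collect ribosomal RNA reads took 5.17% and 4.44% of counts with added sEVs, against 6.16% and 6.48% with dinutuximab.

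By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of 13823 genes were higher and 0 lower, and the smallest adjusted p was 0.360. At an unadjusted p under 0.05, 341 genes were higher and 429 lower, 770 in all against 691 given by chance. limma-voom also called 0 higher and 0 lower (316 and 427 unadjusted), and DESeq2 called 14 higher and 31 lower (272 and 405 unadjusted). All 12 genes of lowest p named in the next paragraph were among those that DESeq2 called. The groups did not overlap in 4779 genes, or 34.6%, where chance gives 33.3%. Leaving out sEV replicate 3 gave 48 higher and 84 lower by edgeR, and leaving out sEV replicate 4 gave 160 higher and 156 lower. In those 2 fits the estimated prior degrees of freedom of the gene variances were infinite, against 6.48 with all 4 libraries, so that all genes shared 1 variance trend.

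The genes of lowest p that were higher with sEVs included enzymes, a lectin and a kinase, and none passed the edgeR quasi-likelihood test (Benjamini-Hochberg adjusted p from 0.360 to 0.463). Hsd11b1, whose product regenerates active glucocorticoid, averaged 1.19 ± 0.635 CPM with dinutuximab and 7.04 ± 0.442 CPM with added sEVs (SD, n = 2), a log2 fold change of 2.57 ± 0.38 (SE). Lbp, the lipopolysaccharide-binding protein, averaged 12.9 and 32.3 CPM (1.32 ± 0.20). Fam111a, a protease, averaged 48.0 and 84.1 CPM (0.81 ± 0.13). The log2 fold change was 1.03 ± 0.18 for Clec10a, 0.85 ± 0.16 for Clk1, a kinase of splicing factors, and 0.96 ± 0.20 for Galnt15, an enzyme of O-linked glycosylation. Among genes of lowest p on the lower side, Slc2a1 (-0.98 ± 0.14) and Hk2 (-0.98 ± 0.15, from 107 to 54.4 CPM) act in glucose uptake and its phosphorylation. Asns, the asparagine synthetase, averaged 122 and 59.2 CPM (-1.04 ± 0.16), and Trib3, a stress-induced pseudokinase, 25.1 and 13.1 CPM (-0.94 ± 0.16). The AP-1 subunit gene Fosl2 averaged 86.7 and 44.2 CPM (-0.97 ± 0.14), and the homeobox gene Meox1 13.3 and 4.16 CPM (-1.68 ± 0.28). In all 12 genes both tumours of a group lay on the same side of both tumours of the other group. The 12 were chosen for lowest p in these libraries. That separation, their DESeq2 calls and their calls in fits without 1 library are therefore no independent evidence. Without sEV replicate 4, edgeR called all 12, with adjusted p between 3.3e-08 for Lbp and 0.0169 for Clk1. Without sEV replicate 3 it called 11 of the 12, with adjusted p between 2.5e-07 for Hsd11b1 and 0.0153 for Trib3. When dinutuximab replicate 3 or dinutuximab replicate 4 was left out, edgeR called 0 genes, so that none of the 12 passed.

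**Figure D1:**
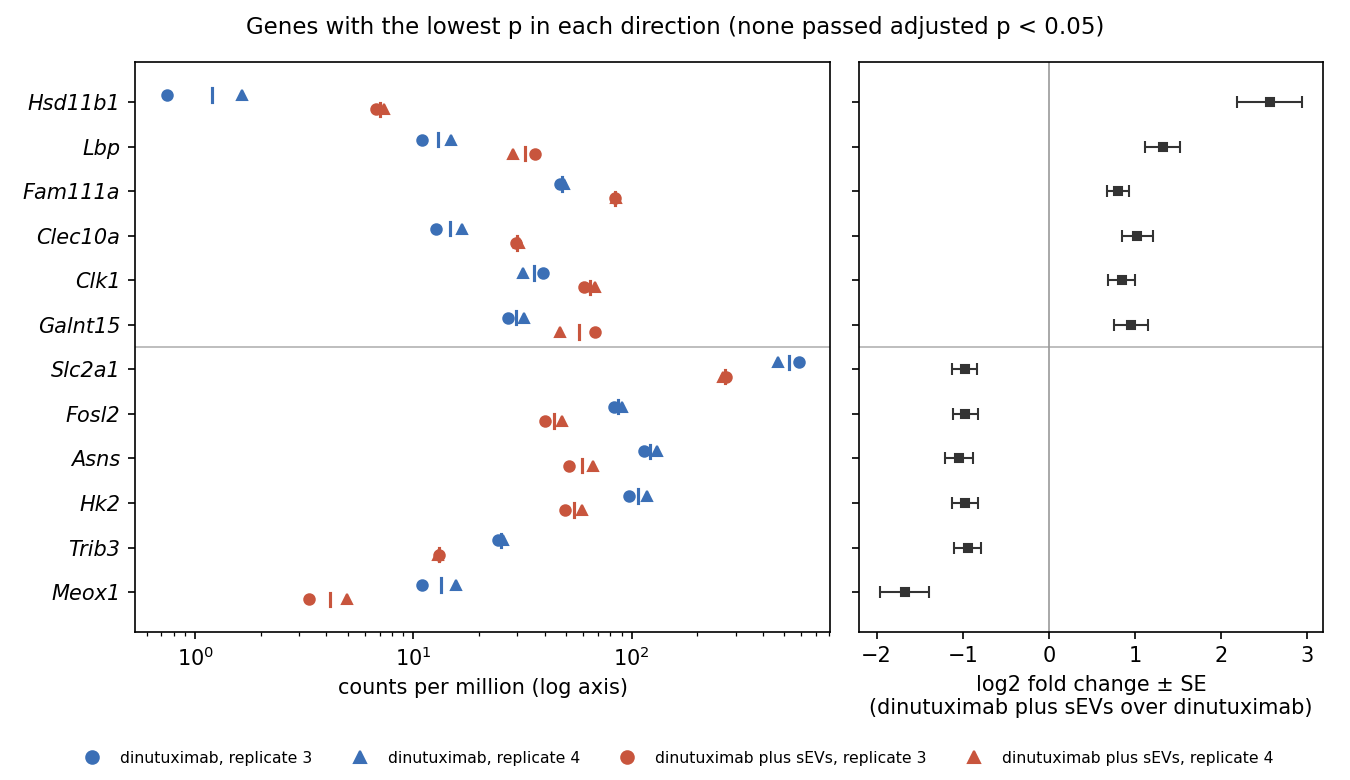
The left panel plots CPM on a log axis for each library (blue, dinutuximab; red, dinutuximab plus sEVs; circle, replicate 3; triangle, replicate 4; vertical tick, group mean) and the right panel the log2 fold change with its SE as a bar, for the 6 genes of lowest p in each direction. In all 12 genes the 2 groups lie apart, from -1.68 for Meox1 to 2.57 for Hsd11b1, and none passed the adjusted test with all 4 libraries.

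All 12 are protein-coding genes, located here on GRCm38. Hsd11b1 (ENSMUSG00000016194) spans 193221634 to 193264075 and Clk1 (ENSMUSG00000026034) 58410189 to 58424066, both on the minus strand of chromosome 1. Lbp (ENSMUSG00000016024) spans 158306493 to 158332852 on the plus strand of chromosome 2, and Trib3 (ENSMUSG00000032715) 152337422 to 152344032 on its minus strand. Slc2a1 (ENSMUSG00000028645) spans 119108711 to 119137983 on chromosome 4 and Fosl2 (ENSMUSG00000029135) 32135801 to 32157842 on chromosome 5, both on the plus strand. Asns (ENSMUSG00000029752) at 7675169 to 7693254 and Hk2 (ENSMUSG00000000628) at 82725025 to 82774454 lie on the minus strand of chromosome 6. On chromosome 11, Clec10a (ENSMUSG00000000318) spans 70156197 to 70170834 on the plus strand and Meox1 (ENSMUSG00000001493) 101877510 to 101894374 on the minus strand. Galnt15 (ENSMUSG00000021903) spans 32028989 to 32062197 on chromosome 14 and Fam111a (ENSMUSG00000024691) 12545740 to 12589768 on chromosome 19, both on the plus strand.

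Of 36 gene lists, camera with the preset correlation called 7 higher and 6 lower with sEVs. With an estimated correlation, and with fry, 0 were higher and 0 lower, and the lowest adjusted p over the lists was 0.399 and 0.529. Of the 36 lists, 9 kept their direction and their call whichever library was left out, and 27 did not. Camera with the preset correlation called 3 of 175 unshifted lists in simulated data, where genes were independent.

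Hypoxia and glycolysis genes were the list of lowest p (camera adjusted p = 1.3e-13). The call was lost with an estimated correlation, where the adjusted p was 0.399. Of its 17 tested members 15 had negative fold changes, 10 had an unadjusted p under 0.05 and 0 passed over all genes. Adjusted over the list alone, 8 were lower, namely Slc2a1, Hk2, Ndrg1, Egln3, Ankrd37, P4ha2, Vegfa and Adm. Egln3, an oxygen-sensing hydroxylase, had a log2 fold change of -0.73 ± 0.21 and Vegfa, the angiogenic growth factor, -0.48 ± 0.15. Pdk1 and Pfkfb3 had positive values. Without dinutuximab replicate 3 the list median was -0.28 (camera adjusted p = 6.4e-06). In the same libraries 9 genes that collect ribosomal RNA reads took 6.16% and 6.48% of counts with dinutuximab and 5.17% and 4.44% with added sEVs, and all 9 had negative fold changes, from -0.65 to -0.26.

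Immediate early and heat shock genes, which also read tissue handling, were lower as a list, with a median of -0.37 and 13 of 14 members negative. The camera adjusted p was 2.2e-08, and the adjusted p was 0.399 with an estimated correlation. Adjusted over the list alone, 2 were lower and 0 higher: the transcription factor genes Egr1 (-0.98 ± 0.17) and Atf3 (-1.10 ± 0.21). Hspa1a, a heat shock gene, had -1.31 ± 0.63. Values near 0 were seen for Fos (-0.10 ± 0.32), Ier2 (-0.04 ± 0.13) and Zfp36 (0.10 ± 0.23). The share of counts in ribosomal RNA read genes was lower in the same tumours, at 5.17% and 4.44% against 6.16% and 6.48%. The 10 tested mitochondrially encoded genes, another reading of RNA quality, had a median of -0.04 (camera adjusted p = 0.817), and none passed adjusted over the list alone. Counts of mt-Co2, mt-Co3 and mt-Atp6 are uncertain, at no more than 1.22 CPM in any library where mt-Co1 had at least 1870 CPM.

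Among stromal lists, endothelial genes were lower, with a median of -0.42 and 13 of 14 members negative (camera adjusted p = 0.00056). With an estimated correlation the adjusted p was 0.675, and without dinutuximab replicate 4 the median was -0.12 and the camera adjusted p 0.259. No endothelial gene passed adjusted over the list alone; Pecam1 had -0.36 ± 0.13 and Flt1 -0.56 ± 0.23. The fibroblast and matrix list was lower (median -0.14, 10 of 18 members negative, camera adjusted p = 0.0202; adjusted p = 0.667 with an estimated correlation). Adjusted over the list alone, 5 of its members were lower: Acta2 (-2.04 ± 0.40) and Tagln (-2.09 ± 0.53), contractile genes of smooth muscle and myofibroblasts, with Col1a2, Postn and Pdgfrb. The matrix genes Col3a1 (0.37 ± 0.14) and Dcn (0.54 ± 0.22) had positive values. Without dinutuximab replicate 4 the fibroblast call was lost at a median of -0.09 (camera adjusted p = 0.0690), without sEV replicate 4 at -0.15 (camera adjusted p = 0.208), and with limma-voom at -0.09 (camera adjusted p = 0.129). Skeletal muscle genes were lower, with all 7 tested members negative and a median of -0.75 (camera adjusted p = 0.00036; adjusted p = 0.399 with an estimated correlation). Only Myh1, a muscle myosin, passed adjusted over the list alone (-2.64 ± 0.46, at most 1.51 CPM in a library). Without dinutuximab replicate 3 the muscle median was -1.88 and without sEV replicate 3 it was -1.16, and without the low-count filter -1.54. The stromal and muscle lists were lower in the tumours where the ribosomal RNA read share (5.17% and 4.44% against 6.16% and 6.48%) and the immediate early and heat shock list (median -0.37) were also lower.

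Markers of the mesenchymal state of neuroblastoma were lower as a list, with a median of -0.09 and 9 of 14 members negative (camera adjusted p = 0.0090; adjusted p = 0.591 with an estimated correlation). Adjusted over the list alone, 2 were lower, Fosl2 and Meox1, and the other 12 did not pass. The call was lost without dinutuximab replicate 4 (median 0.01, camera adjusted p = 0.172), without sEV replicate 4 (-0.05, 0.0908) and with limma-voom (-0.06, 0.0757), and the median was -0.15 without dinutuximab replicate 3. It was also -0.06 with total-count scaling and with a filter of 1 CPM. The ribosomal RNA read share (5.17% and 4.44% against 6.16% and 6.48%) and the immediate early and heat shock list (median -0.37) were lower in the same tumours. The adrenergic list was not called (median -0.02, mean -0.35, camera adjusted p = 0.108), with Dlk1 (-1.35 ± 0.39) among the members lower adjusted over the list alone. Without sEV replicate 3 its median was -0.37 (camera adjusted p = 0.0064). Only 9 of 23 adrenergic markers passed the low-count filter, and 11 of the other 14 had at most 3 counts in every library. Th, the tyrosine hydroxylase gene, had 0, 3, 1 and 0 counts. Hand2, at between 145 and 172 CPM, and Isl1, at between 15.7 and 21.4 CPM, were measured in all 4.

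Genes of red blood cells were higher with sEVs as a list (median 1.19, all 6 tested members positive, camera adjusted p = 1.9e-10). The adjusted p was 0.399 with an estimated correlation. Adjusted over the list alone, all 6 were higher and 0 lower, including Hbb-bs (0.94 ± 0.29) and Hba-a1 (1.07 ± 0.33), which encode globin chains, and Alas2 (1.32 ± 0.52), an enzyme of haem synthesis. Levels were low, at most 45.6 CPM for Hbb-bs, and the globin genes have near-identical copies whose counts are uncertain. Without sEV replicate 3 the list median was 0.66 (camera adjusted p = 6.3e-07). The tumours with higher red blood cell genes had the lower ribosomal RNA read share (5.17% and 4.44% against 6.16% and 6.48%) and the lower immediate early and heat shock list (median -0.37).

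Alternatively activated macrophage genes were higher as a list, with 14 of 16 members positive (camera adjusted p = 4.4e-06; adjusted p = 0.510 with an estimated correlation). Clec10a and Mgl2 (0.65 ± 0.13), which encode related lectins, passed adjusted over the list alone, and the other 14 did not. Mrc1, the mannose receptor gene, had 0.39 ± 0.17 and Arg1, arginase, -0.11 ± 0.34. Without sEV replicate 3 the median was 0.15 (camera adjusted p = 0.0147), and without sEV replicate 4 it was 0.57. General macrophage genes had a median of 0.22 with 14 of 16 positive (camera adjusted p = 0.00035; adjusted p = 0.667 with an estimated correlation). None passed adjusted over the list alone: Fcgr1 had 0.47 ± 0.15 and Adgre1, which encodes F4/80, -0.04 ± 0.14. Without dinutuximab replicate 3 the macrophage median was 0.15 and the call was lost (camera adjusted p = 0.217), and without dinutuximab replicate 4 it was 0.36. Genes of Fc receptors and phagocytosis had a median of 0.22 (camera adjusted p = 0.0051; adjusted p = 0.669 with an estimated correlation), with 13 of 15 positive and 0 past the threshold adjusted over the list alone. Without dinutuximab replicate 3 this median was 0.07 and the call was lost (camera adjusted p = 0.274). These 3 lists were higher where the ribosomal RNA read share (5.17% and 4.44% against 6.16% and 6.48%) and the immediate early and heat shock list (median -0.37) were lower.

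Complement genes had a median of 0.26 with 11 of 13 positive (camera adjusted p = 0.00056; adjusted p = 0.399 with an estimated correlation). Adjusted over the list alone, 3 were higher: Cd59a (1.04 ± 0.26), an inhibitor of the membrane attack complex, Cfp (0.44 ± 0.13), properdin, and C1s1 (0.99 ± 0.29), a protease of the classical pathway. Without dinutuximab replicate 4 the complement median was 0.48 (camera adjusted p = 0.00069). Type I interferon response genes had a median of 0.23 with 18 of 20 positive (camera adjusted p = 0.0022; adjusted p = 0.711 with an estimated correlation), and none passed adjusted over the list alone, Mx1 (0.86 ± 0.21) being nearest. This list moved with single libraries: the median was 0.73 without dinutuximab replicate 3, 0.47 without sEV replicate 3, 0.03 without sEV replicate 4 (camera adjusted p = 0.412) and -0.11 without dinutuximab replicate 4 (camera adjusted p = 0.704). Genes of ganglioside synthesis, the pathway that makes GD2, had a median of 0.18 with 10 of 11 positive (camera adjusted p = 0.0162; adjusted p = 0.706 with an estimated correlation). None passed adjusted over the list alone. St8sia1, the GD3 synthase gene, averaged 4.52 ± 0.158 CPM with dinutuximab and 9.93 ± 4.05 CPM with added sEVs (SD, n = 2), a log2 fold change of 1.14 ± 0.30, and B4galnt1, the GM2 and GD2 synthase gene, had 0.33 ± 0.16. The edgeR adjusted p of St8sia1 was 0.614 with all libraries. Its log2 fold change was 0.64 without sEV replicate 3, where it was not called (edgeR adjusted p = 0.9999), and its adjusted p was 0.00019 without sEV replicate 4 and 0.0031 without the low-count filter. Without dinutuximab replicate 3 or 4 its log2 fold change was 1.10 or 1.17 (edgeR adjusted p = 0.854 and 0.838). The ganglioside call was lost without dinutuximab replicate 3 (median 0.16, camera adjusted p = 0.176) and without sEV replicate 3 (0.08, 0.403). The 9 ribosomal RNA read genes took a lower share of counts in the sEV group, where these lists were higher (5.17% and 4.44% against 6.16% and 6.48%).

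**Figure D2:**
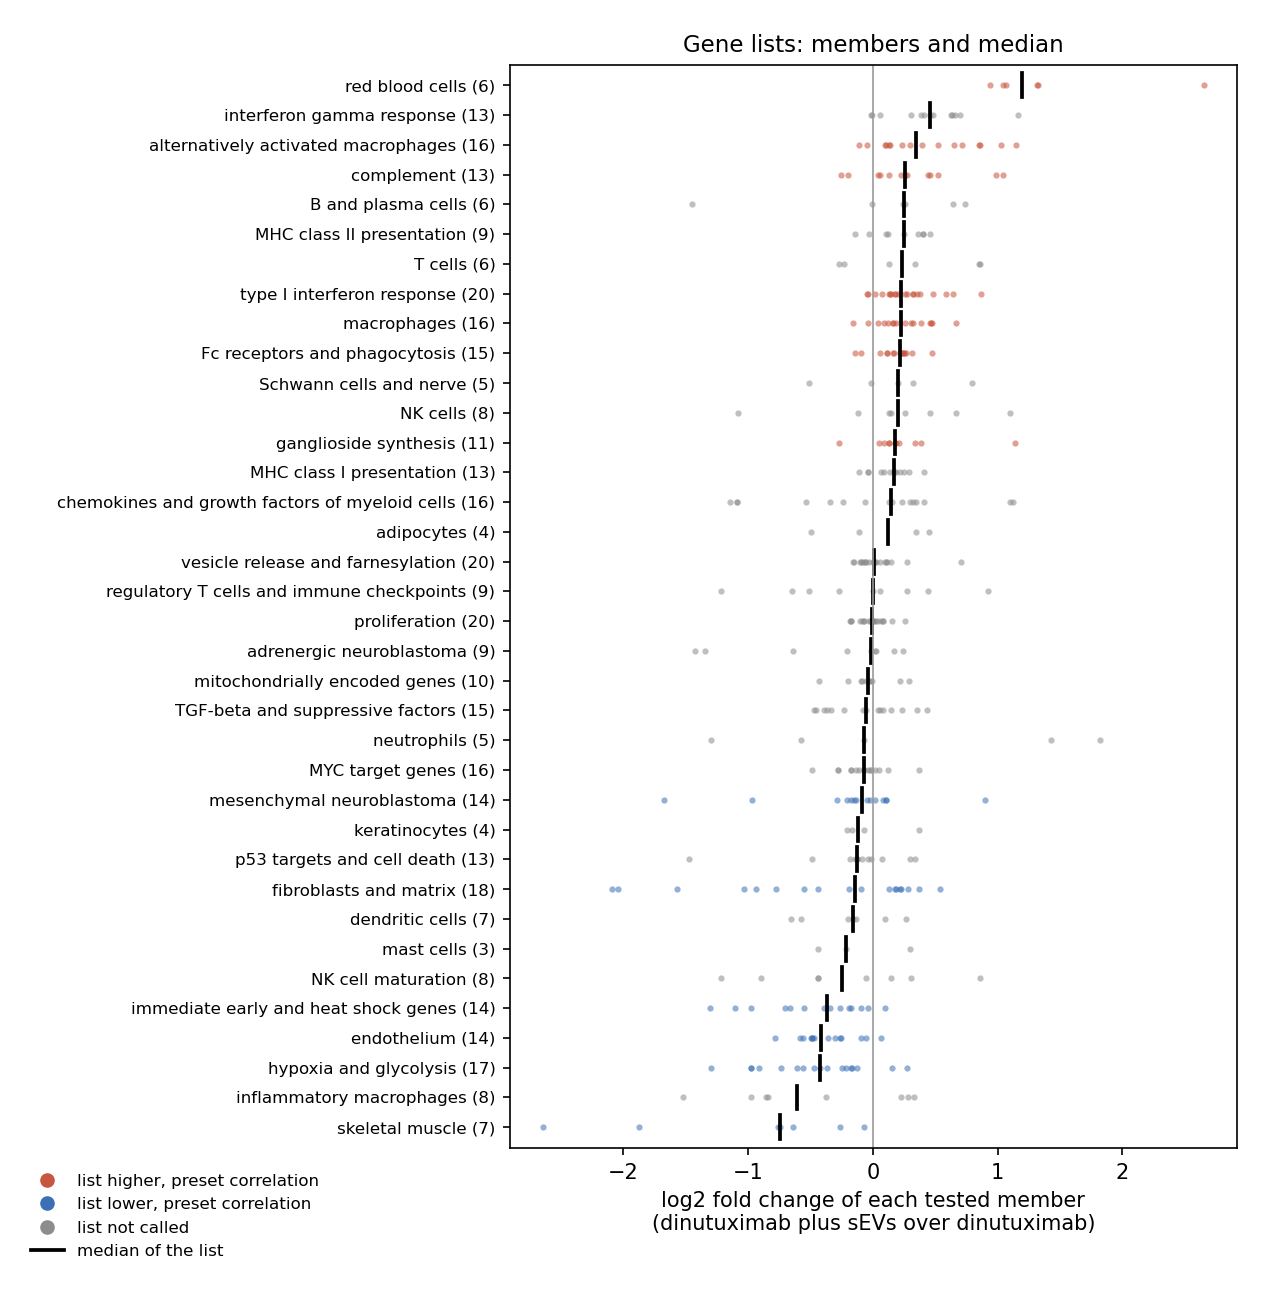
Each dot is the log2 fold change (dinutuximab plus sEVs over dinutuximab) of a tested member of a gene list, each black tick the median of the list, and numbers in brackets count the tested members. Red lists were called higher and blue lists lower by camera with the preset correlation, from a median of -0.75 for skeletal muscle to 1.19 for red blood cells, and grey lists were not called.

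Lists of antigen presentation and lymphocytes were not called in the model with the group as its only term and the low-count filter. T cell genes had a median of 0.23 (camera adjusted p = 0.834), and few reads came from them: Cd8a, the CD8 alpha chain gene, had 7, 17, 6 and 43 counts (0.85 ± 0.80). MHC class II genes had a median of 0.25 (0.380), MHC class I genes 0.17 (0.177) and interferon gamma response genes 0.46 (0.0683), by the same camera test. Each of these lists gained a call when a single library was left out. Such a fit holds unequal tumour numbers in its groups, and each of these lists had a higher median in tumours numbered 4 than 3. For class II the log2 difference was 1.67 with dinutuximab and 1.92 with sEVs, and for T cells 1.11 and 1.90. Without sEV replicate 3 the medians were 1.45 for T cells, 0.73 for MHC class II, 0.41 for MHC class I and 1.01 for interferon gamma, with camera adjusted p of 3.9e-09, 8.3e-27, 2.0e-07 and 6.0e-26. Without the low-count filter the interferon gamma list was called higher (0.47, camera adjusted p = 0.0362). Without sEV replicate 4 the medians were -1.22 for T cells, -0.86 for MHC class II and -0.44 for interferon gamma, with camera adjusted p of 0.0192, 5.5e-05 and 0.0295. Without dinutuximab replicate 4 they were 1.47 for T cells, 1.45 for MHC class II and 0.35 for MHC class I, with camera adjusted p of 0.0401, 0.00018 and 0.0123. B and plasma cell genes had 0.25 (camera adjusted p = 0.817), and 0.58 (0.00027) without sEV replicate 3. No member of these lists passed adjusted over the list alone.

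Natural killer cell genes had a median of 0.20 (camera adjusted p = 0.616) and genes of their maturation -0.25 (0.616). Prf1, which encodes perforin, averaged 1.87 ± 0.941 CPM with dinutuximab and 0.879 ± 0.325 CPM with added sEVs (SD, n = 2), a log2 fold change of -1.08 ± 0.48, and Xcl1 had 1.10 ± 0.53. Ncr1, a natural killer receptor gene, had 10, 8, 11 and 8 counts and was below the filter. Genes of regulatory T cells and immune checkpoints had a median of 0.00 and a mean of -0.11, with the test on the lower side (0.722), and Cd274, which encodes PD-L1, had -0.28 ± 0.32. Dendritic cell genes had a median of -0.16 (0.298). Neutrophil genes had a median of -0.07, a mean of 0.26 and a test on the higher side (0.669). Mast cell genes, with 3 tested, had a median of -0.22 and a mean of -0.12 with the test on the higher side (0.817). The mast cell list was called higher without dinutuximab replicate 4 (median 2.60, camera adjusted p = 0.0060) and lower without dinutuximab replicate 3 (-1.12, 0.0499) and without sEV replicate 3 (-1.78, 0.0238). Values in brackets after a median are camera adjusted p, and no member of these 6 lists passed adjusted over the list alone.

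Inflammatory macrophage genes had a median of -0.61 (camera adjusted p = 0.173), with Ptgs2 (-1.53 ± 0.55), Tnf (-0.98 ± 0.40) and Il23a (-0.84 ± 0.34) at an unadjusted p under 0.05 and none past the threshold adjusted over the list alone. The list was called lower without dinutuximab replicate 4 (median -1.10, camera adjusted p = 7.8e-05) and without sEV replicate 3 (-0.91, 0.0034). Chemokines and growth factors of myeloid cells had a median of 0.14, a mean of -0.02 and a test on the higher side (camera adjusted p = 0.346). Ccr2 (1.12 ± 0.31) and Ccl5 (1.10 ± 0.42) had positive values and Ccl3 (-1.09 ± 0.40), Ccl4 (-1.09 ± 0.44) and Cxcl12 (-1.14 ± 0.45) negative ones, and none passed adjusted over the list alone. This list was called higher without dinutuximab replicate 3 (0.52, 2.7e-05) and lower without dinutuximab replicate 4 (-0.07, 0.0070). Genes of TGF-beta and suppressive factors had a median of -0.06 (camera adjusted p = 0.173), and -0.30 (0.0477) without sEV replicate 4, with none past the threshold adjusted over the list alone.

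Lists of proliferation, MYC target, p53 and vesicle genes were not called. Proliferation genes had a median of -0.01 (camera adjusted p = 0.844), MYC target genes -0.07 (0.239), p53 and cell death genes -0.13 (0.173), and genes of vesicle release and farnesylation 0.00 (0.817). The proliferation list was called higher without sEV replicate 3 (0.10, 0.0183) and lower without sEV replicate 4 (-0.19, 0.0302). In the p53 list Gdf15 (-1.48 ± 0.39) and Sesn2 (-0.49 ± 0.16) had an unadjusted p under 0.05. Mki67, a proliferation marker gene, had -0.17 ± 0.20, and Fntb, a subunit of the farnesyltransferase that tipifarnib inhibits, -0.16 ± 0.13. Mycn averaged 148 ± 20.1 CPM with dinutuximab and 150 ± 14.9 CPM with added sEVs (SD, n = 2), where reads of a human MYCN transgene, if counted, were not told apart. Col1a1 had -0.44 ± 0.17 and Fcgr4, an activating Fc receptor gene, 0.12 ± 0.30. Keratinocyte genes had a median of -0.12 and a mean of -0.02 with the test on the higher side (0.930), and 0.20 (0.0130) without sEV replicate 4. Adipocyte genes had a median of 0.12 (0.323) and Schwann cell and nerve genes 0.20 (0.586). No member of these lists passed adjusted over the list alone.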

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

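Leaving out the ribosomal RNA read genes was the only alternative chosen after their levels were seen, and it moved no count of calls. The count of called genes was 0 higher and 0 lower with edgeR at all 4 scalings tried, with limma-voom, with a filter of 1 CPM, with robust dispersions, at an adjusted p of 0.1, against a minimum fold of 1.5, without mitochondrial and the 20 most abundant genes, and from the tables per sample. It was 14 higher and 31 lower with DESeq2, and 107 higher and 155 lower without the low-count filter, where 22003 genes were tested and the prior degrees of freedom were infinite. Leaving out 1 library gave between 0 and 160 higher and between 0 and 156 lower, the calls coming without sEV replicate 3 or 4, where the prior degrees of freedom were also infinite. The median log2 fold change of all genes was 0.00 with TMM, -0.00 with relative log expression, 0.01 with upper quartile and 0.04 with total-count scaling.

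With the tumour number as a replicate block, 21 genes were higher and 46 lower by edgeR, and the prior degrees of freedom were 14.7. All 12 genes of lowest p in the main fit were among the genes called under the block. The B and plasma cell list turned its test to the lower side with a median of 0.25. The MHC class II (0.24) and interferon gamma (0.31) lists gained a call under the block and no called list lost one. The labels do not say that numbers pair the tumours, there are only 2 pairs, and the correlation across genes of the deviations of equal numbers was 0.07, so the block stands as an alternative only.

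For gene lists, camera with an estimated correlation called 0 higher and 0 lower, as did fry, which also reads the list alone. Leaving out 1 library gave between 5 and 12 lists higher and between 5 and 9 lower, against 7 and 6 with all libraries. Hypoxia and glycolysis, immediate early and heat shock, skeletal muscle, red blood cell, complement and alternatively activated macrophage lists kept direction and call in 14 of 16 alternatives, the exceptions being estimated correlation and fry. The test changed direction for these lists that were not called, and the cause was not tested: Schwann cells and nerve without the low-count filter (median -0.52), natural killer cells (0.14) and B and plasma cells (0.23) with a filter of 1 CPM, and neutrophils both without mitochondrial and the 20 most abundant genes (-0.33) and without ribosomal RNA read genes (-0.33).

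Results whose fold change or list test turned direction when 1 library was left out are given as the range over the 4 fits. The T cell, MHC class I, MHC class II and interferon gamma lists had higher medians in tumours numbered 4 than 3, in both groups. Leaving out 1 library left the numbers unequal between the groups, so the ranges of these lists hold that difference. The same holds for Arg1, lower in number 4 (-0.90 ± 0.14), and for 3 further lists. Their medians for number 4 over 3, with dinutuximab and with sEVs, were 0.70 and 0.58 for regulatory T cells, 0.67 and 0.24 for dendritic cells, and -0.66 and -0.24 for chemokines. Camera called these 3 lists between the numbers with the preset correlation and not with an estimated one. For the remaining results the cause was not tested. Log2 fold changes ranged from -0.76 to 0.33 for Arg1, -0.60 to 0.035 for Cd274, -0.39 to 0.48 for Fcgr4, -0.11 to 0.17 for Mycn, -0.19 to 0.083 for Adgre1, -0.51 to 0.091 for Mki67 and -1.06 to 1.65 for Cd8a. List medians ranged from -1.22 to 1.47 for T cells, -1.78 to 2.60 for mast cells, -0.86 to 1.45 for MHC class II, -0.21 to 0.41 for MHC class I, -0.19 to 0.10 for proliferation, -0.23 to 0.47 for Schwann cells and -0.15 to 0.015 for mitochondrially encoded genes. They ranged from 0.18 to 0.41 for natural killer cells, -0.18 to 0.49 for natural killer maturation, -0.56 to 0.19 for regulatory T cells, -0.45 to 0.58 for B and plasma cells, -0.60 to 0.47 for neutrophils and -0.30 to 0.21 for dendritic cells. They ranged from -0.11 to 0.73 for the type I interferon response, -0.069 to 0.52 for chemokines, -0.067 to 0.060 for vesicle release and -0.44 to 1.01 for the interferon gamma response.

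At 1 CPM, T cells, neutrophils, mast cells and Cd8a had too few counts to give a value, and without mitochondrial genes their own list had none. Many lymphocyte markers had under 20 counts in a library, which limits their precision at this depth.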

Other observations

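Tests of a single library, of tumour cell genes, of immediate early genes, of B cell genes and of interferon gamma genes were chosen after the results were seen. The tests of further hypoxia, amino acid and mural genes and of other splits were chosen before their values were seen. All of the patterns came from the same 4 libraries, so each explanation is a hypothesis.

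MHC class II genes, which present antigen to CD4 T cells, differed between the tumour numbers in both groups. H2-Eb1 was 4.19-fold higher in tumours numbered 4 than in tumours numbered 3, H2-Aa 3.88-fold, H2-Ab1 3.71-fold and the invariant chain gene Cd74 3.63-fold, by an edgeR quasi-likelihood test between the numbers with Benjamini-Hochberg adjusted p between 0.0127 and 0.0143. H2-Eb1 was at 47.4 and 160 CPM in dinutuximab tumours 3 and 4, and at 45.6 and 229 CPM in sEV tumours 3 and 4. These were the 4 genes that test called, and at an unadjusted p under 0.05 the number split had 905 genes. The class II list median was 1.67 higher in number 4 with dinutuximab and 1.92 higher with sEVs, and the T cell list 1.11 and 1.90, on the log2 scale. Ccl12 (-1.23 ± 0.15) and Arg1 (-0.90 ± 0.14) had lower values in number 4 and did not pass. The labels do not say what the number stands for.

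Lymphoid tissue in the sampled tumour is a candidate explanation of the class II difference, since B cells carry class II. The B and plasma cell list was 0.23 ± 0.49 higher in number 4 with dinutuximab and 0.44 ± 0.65 with sEVs (log2 median ± SE over 6 genes), too imprecise to exclude a rise of 1. The bound first set against this explanation ignored these errors and was met by both medians, and it was replaced after they were seen. An interferon gamma response, which induces class II through Ciita, may also account for it: the interferon gamma list was 0.25 higher in number 4 with dinutuximab and 1.35 with sEVs (camera adjusted p = 1.2e-06 between the numbers; adjusted p = 0.815 with an estimated correlation). Both remain open, and a difference in litter, cage, day or tumour size between the numbers was not tested.

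The hypoxia and glycolysis list stayed lower with sEVs whichever library was left out. Its median nearest to 0 was -0.28, without dinutuximab replicate 3. That list was picked for its lowest p in these libraries, and the bound of -0.2 was set after the results were seen, which favours this outcome. A smaller share of tumour cells would lower tumour cell genes about as much as the hypoxia list, whose median was -0.43. Over 24 tumour cell and proliferation genes the median was -0.0023 ± 0.101 (SE allowing for their estimated correlation of 0.437). It ranged from -0.14 to 0.10 when 1 library was left out. For these genes the values argue against a fall as large as that of the hypoxia list. They are too imprecise to exclude the -0.2 set as the bound, so a smaller part of the pattern stays open. Tissue handling before freezing may account for the pattern, since the immediate early and heat shock list had a median of -0.37 with 13 of 14 negative (camera adjusted p = 2.2e-08, and 0.399 with an estimated correlation). A subset of 7 of the 14 genes, chosen after their values were seen, was tested first. Its median of -0.18 fell short of -0.2. The full list passed -0.2, but that bound was also set after the results were seen, so it cannot decide for or against handling. A lower hypoxia response at large may account for it too. The 22 hypoxia genes outside the list had a median of -0.20 with 17 negative (camera adjusted p = 2.1e-06, and 0.158 with an estimated correlation; fry adjusted p = 0.203). They were read in the same libraries, so these values go with a lower response but are no independent test of it. Tumour size, necrosis and blood supply were not tested.

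The 4 libraries make only 3 splits into groups of 2, too few for a share under 0.05, so the count of lists called can be set only beside the other splits. Of these splits 1, the real one, called as many as 13 lists by camera with the preset correlation, and the highest other, the split by tumour number, called 12. The remaining split called 8. By edgeR the split by tumour number called 4 genes, where the real split called 0. With an estimated correlation each split called 0. The hypoxia list had medians of -0.20 and -0.14 in the other splits (camera adjusted p = 0.0485 and 0.0816), against -0.43 in the real one. That list was picked for its lowest p in the real split, which favours the real split here. The lowest camera adjusted p of any list was 1.3e-13 in the real split. It was 7.2e-59 in the split by tumour number and 1.0e-14 in the remaining split, both lower than in the real one.

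Asns and Trib3 among the genes of lowest p are targets of the amino acid response driven by ATF4, so a lower response at large was tested as a hypothesis on 25 further response genes. Their median was -0.32, 24 of 25 were negative and 10 had an unadjusted p under 0.05 (camera adjusted p = 2.1e-12 with the preset correlation). These values go with a lower response but are no independent test of it. The adjusted p was 0.158 with an estimated correlation and 0.203 with fry. Acta2 and Tagln prompted the hypothesis of fewer mural or contractile cells. Over 15 further mural and smooth muscle genes the median was -0.54 with 14 negative (camera adjusted p = 1.6e-06; adjusted p = 0.158 with an estimated correlation and 0.203 with fry), and Des among them is also a skeletal muscle gene. Lower expression within such cells, or a different region sampled, may give the same values. Both groups of genes were lower in the tumours where the immediate early and heat shock list (median -0.37), the ribosomal RNA read share (5.17% and 4.44% against 6.16% and 6.48%), the skeletal muscle list (-0.75) and the endothelial list (-0.42) were also lower.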
